A study of Saccharomyces cerevisiae with 10 samples.

How the data were processed

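Per the labels' protocols, cells were grown in YPD and treated, total RNA was isolated with hot acid phenol and purified on columns, and cDNA was made and labelled through an indirect labelling kit. The authors scanned 2-colour Agilent arrays and extracted them with Feature Extraction 10.5.1.1, per the file headers. The deposited scanner files give an intensity per spot and channel, its local background and marks for spots above background, saturated or non-uniform; in these files Agilent's log10 ratio is Cy5 over Cy3 after the software's own processing, per the file headers. A deposited table of the authors' processed values was also used, which the values show to be a log10 ratio per spot. Its scale, centring and direction are not stated: they were read from a comparison with the scanner files, and the centring stays unknown, with column medians of 0.00 to 0.05 in size on the log10 scale. Columns for the arrays labelled xbp1Δ and phd1Δ replicate 1 matched their own arrays with rank correlations of -0.98, 0.91 and -0.95, so their forward columns ran opposite to Cy5 over Cy3. The column of butanol replicate 2 matched the array of butanol replicate 1 (-0.94, and -0.75 by duplicate spots). The column of butanol replicate 1 matched neither butanol array by duplicate spots (0.02 and -0.12) but had a rank correlation of 0.75 with the array of butanol replicate 2. The 2 butanol arrays themselves had a correlation of 0.750 across genes, so that value cannot show whether the 2 columns were exchanged. Weaker matches with their own arrays were those of phd1Δ replicate 2 (0.44) and of the self comparison (-0.59 and 0.46). The column labelled rox1Δ replicate 1 had a rank correlation of -0.85 with its own array. By duplicate spots, however, it matched the array of self comparison replicate 1 better (-0.44 against -0.30). The column labelled rox1Δ replicate 2 matched none of the 10 arrays. The correlations of columns with arrays are across spots, which are not independent replicates.

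Each of the 10 files holds 13048 spots, 536 of them control spots. Median signals were used because mean signals were present in 4 of the 10 files. Background was corrected with normexp (offset 50) over all spots, and ratios were normalized within each array by loess with control spots at weight 0. Control spots and spots marked as non-uniform or population outliers (1 to 79 per array) were left out, duplicate spots were averaged, and probes were kept if well above background in a channel of at least 2 arrays, which left 6246 of 6256. Gene names came from the array design and from a RefSeq gene table of assembly R64, which held 5756 of the 6256 systematic names; 500 kept the name of the array. No genome was used, and no coordinates are given.

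All 10 arrays were fitted together with limma 3.58.1 in R 4.3.3, with a coefficient per comparison and a gene-specific dye term, since 2 arrays alone leave 1 degree of freedom without a dye term; 4 residual degrees of freedom were joined by 4.42 prior ones, and the prior SD was 0.218. Tests were two-sided, with Benjamini-Hochberg adjustment within a comparison and a threshold of 0.05. No gene had a dye term past that threshold. Whether replicates came from separate cultures is stated only as biological replicate in the labels. The main values use log2 ratios computed here from the deposited intensities. For each ± value the error is the standard error of the limma fit. For a gene that passed the test and was well above background on no array of a group, the fold is given as a lower bound; where a single array was affected, the text says so.

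Of 43 gene lists fixed before the data were examined, 37 had at least 5 tested members and were tested with camera (preset correlation 0.01, and with an estimated correlation) and with fry. Camera sets a list against all other genes; fry tests whether its genes move one way, without such a comparison. Named genes were chosen by a rule also fixed before the data were examined: the deleted gene and its neighbours, the 10 largest increases and 10 largest decreases among genes past the threshold with the same sign on both arrays, and up to 4 members with the largest ratio of each list that passed camera or that the comparison was about. The fits, the lists, the named gene rule and most alternatives were set before the data were examined; the direction of the deletion comparisons (first fixed from the labelled dyes), the fits within slides and scans, the fit without the doubted array labelled rox1Δ replicate 2 and the removal of an intensity trend from the authors' values were chosen after.

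Chromosome shifts were tested with 100000 permutations of gene positions. Slides and scans served as batches: slide 1 held 8 arrays and slide 2 held 2, scan 1 held 4 and scan 2 held 6. Alternatives covered background correction, normalization, filters, outlier spots, the dye term, batch blocks, each replicate left out, the variance prior and the authors' values. The gene test was tested on simulated data made from the butanol comparison (6237 genes, 200 changed): 12 of 67 genes changed by a log2 of 0.5 were recovered, 61 of 67 changed by 1 and 66 of 66 changed by 2, while 7 unchanged genes were called. In the simulated data a shifted list was called and 0 of 40 unchanged lists were. On the real arrays of wild type against itself, camera with its preset correlation called 4 of 37 lists. The simulated count therefore does not give the rate of false list calls in these data. Nor do the simulated gene calls give the rate of false gene calls, since those data were drawn from the fitted model itself. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.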

Results

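Transcript levels were measured in budding yeast on 10 Agilent arrays, each hybridised with a pair of RNA samples labelled with Cy5 and Cy3. The strains were BY4742, a common laboratory wild type of mating type alpha, and BY4742 derivatives from a commercial deletion library in which XBP1, PHD1 or ROX1 had been replaced by a G418 resistance cassette. Xbp1, Phd1 and Rox1 are DNA-binding transcription factors: Xbp1 is a stress-induced repressor, Phd1 is an activator linked to filamentous growth, and Rox1 is the repressor of low-oxygen genes. There were 5 comparisons, with 2 arrays each, and the 2 arrays of a comparison came from 2 biological replicates with the dyes exchanged, per the labels. The deletion strains were set against wild type in 3 treatments: peroxide at 0.4 mM during 20 min (labelled xbp1Δ), butanol at 1% during 90 min (labelled phd1Δ) and peroxide at 4 mM during 30 min (labelled rox1Δ). Wild type in 1% butanol for 90 min was set against wild type in rich medium (YPD), and wild type in YPD was set against itself. The treatments of the deletion strains were those under which binding of the same factors to DNA had been mapped, so these comparisons asked which genes depended on each factor in that condition. The butanol comparison gave the response of the wild type, and the self comparison gave the background.

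Each array carried 12512 gene spots, 2 for each of 6256 probes. The median spot signal of an array lay between 208 and 3720 in Cy3 and between 197 and 2509 in Cy5, and between 87.1% and 99.8% of gene spots per channel were well above background. The dimmest Cy5 channel was that of phd1Δ replicate 2, and the dimmest Cy3 channel was that of the array labelled rox1Δ replicate 1. No spot was saturated. With 2 arrays per comparison, the number of arrays limited the precision, and the median standard error of a fitted log2 ratio was 0.15.

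The deleted genes were examined on every array before the comparisons. PHD1 was low on both arrays labelled phd1Δ, with log2 ratios of -4.65 and -2.86, and between -0.38 and 0.25 on the other 8 arrays. ROX1 was low on the array labelled rox1Δ replicate 1, at -2.84 against a Cy3 channel not well above background, but was at 0.09 on the array labelled rox1Δ replicate 2. XBP1 was at -0.23 and -0.21 on the arrays labelled xbp1Δ, where its probe was 31.2 to 86.9 times its local background in every channel. These ratios are deletion over wild type in the direction of the authors' processed values, which is opposite to the direction that the labelled dyes give for the 3 deletion comparisons. On both arrays labelled phd1Δ, PHD1 was dim in the channel that the labels assign to the wild type. Its signal there was 5.0 and 1.3 times the local background, against 72.8 and 64.8 in the other channel. These values argue against the dyes as labelled for that comparison. ROX1 on the array labelled rox1Δ replicate 1 was likewise dim, on a lone array, so that direction is likely and not settled. For the array labelled rox1Δ replicate 2 the authors' column matched no array, and the direction was carried over from replicate 1. For the library labelled xbp1Δ it rests on the authors' values alone. With the dyes as labelled, every sign in these 3 comparisons would turn, and PHD1 would be at 3.76. The butanol comparison was printed with the dyes as labelled, and no deleted gene was there to check them. Of its 1427 called genes, 317 were also called in the authors' values, 0 of them with the opposite sign. Its direction rests on the labels and on those values. If its 2 arrays had been exchanged, the labelled dyes would give the opposite signs. Because ROX1 and XBP1 did not match their labels on 3 arrays, rox1Δ and xbp1Δ are used here as labels and not as shown genotypes. The place of the XBP1 probe within the gene was not examined here.

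**Figure D1:**
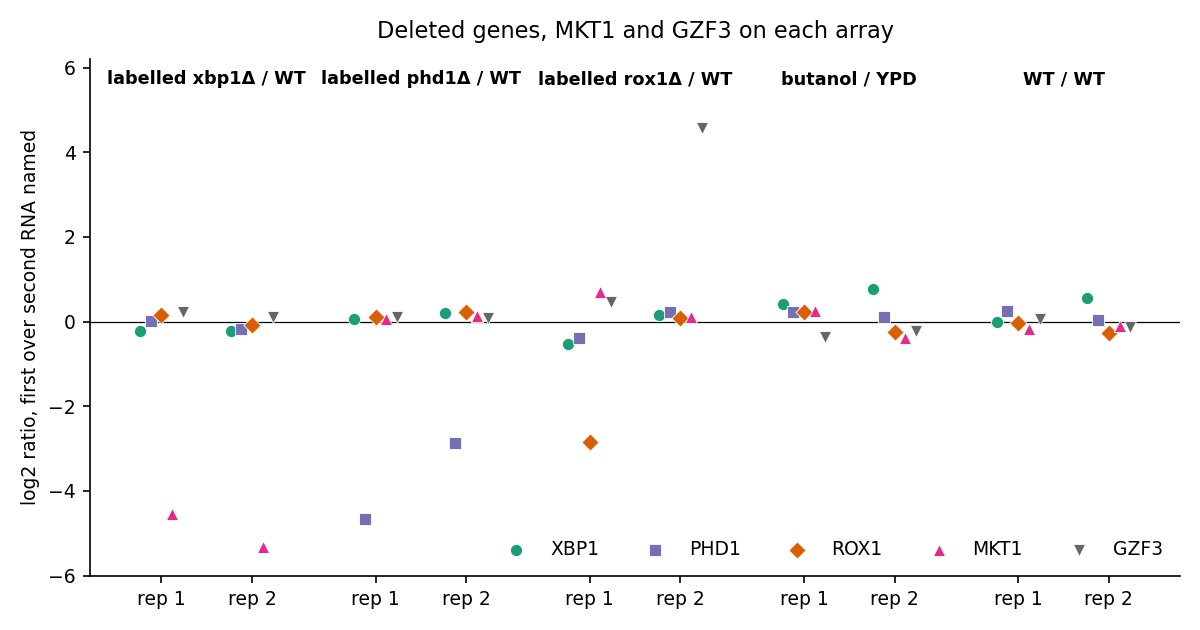
Log2 ratio (y axis) of XBP1, PHD1, ROX1, MKT1 and GZF3 on each of the 10 arrays (x axis, by comparison and replicate), 1 point per gene and array, mean of its duplicate spots. PHD1 was at -4.65 and -2.86 on the arrays labelled phd1Δ, ROX1 at -2.84 on 1 of the 2 labelled rox1Δ, MKT1 at -4.55 and -5.32 on those labelled xbp1Δ, and GZF3 at 4.57 on the array labelled rox1Δ replicate 2.

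In wild type given 1% butanol, many genes of amino acid synthesis and general stress were higher than in YPD, as were some of alcohol metabolism, and many genes of translation and some of mating were lower; no list of genes passed its set test with an estimated correlation. ARO10, the decarboxylase of the pathway that turns amino acids into fusel alcohols, had the largest increase (log2 4.17 ± 0.12 SE, n = 2 arrays, 18.0-fold). Among the other large increases were those of SNZ1 and SNO1 of vitamin B6 synthesis (14.5-fold and 8.41-fold) and of OPI3, a phospholipid methyltransferase gene (3.75 ± 0.13, 13.4-fold). GPG1 was 12.0-fold higher, the membrane stress protein gene HSP12 12.0-fold, ARO5 9.95-fold, ARG1 of arginine synthesis 9.95-fold and the peroxisomal citrate synthase gene CIT2 7.52-fold; the glyceraldehyde-3-phosphate dehydrogenase gene TDH1 was at 3.46 ± 0.23. The largest decrease was that of MF(ALPHA)2, which encodes the alpha mating pheromone (-4.00 ± 0.39). LEU1 of leucine synthesis was 7.59-fold lower, the low-affinity glucose transporter gene HXT1 6.99-fold and the cell wall mannoprotein gene TIR1 6.69-fold. ZEO1, HO, YDL241W, QDR2, RPS14B and PHO3 were 3.54-fold to 4.37-fold lower. Among 6246 genes tested in limma, 778 were higher and 649 lower at an adjusted p under 0.05, of which 249 and 124 changed at least 2-fold, and 2356 genes had an unadjusted p under 0.05.

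**Figure D2:**
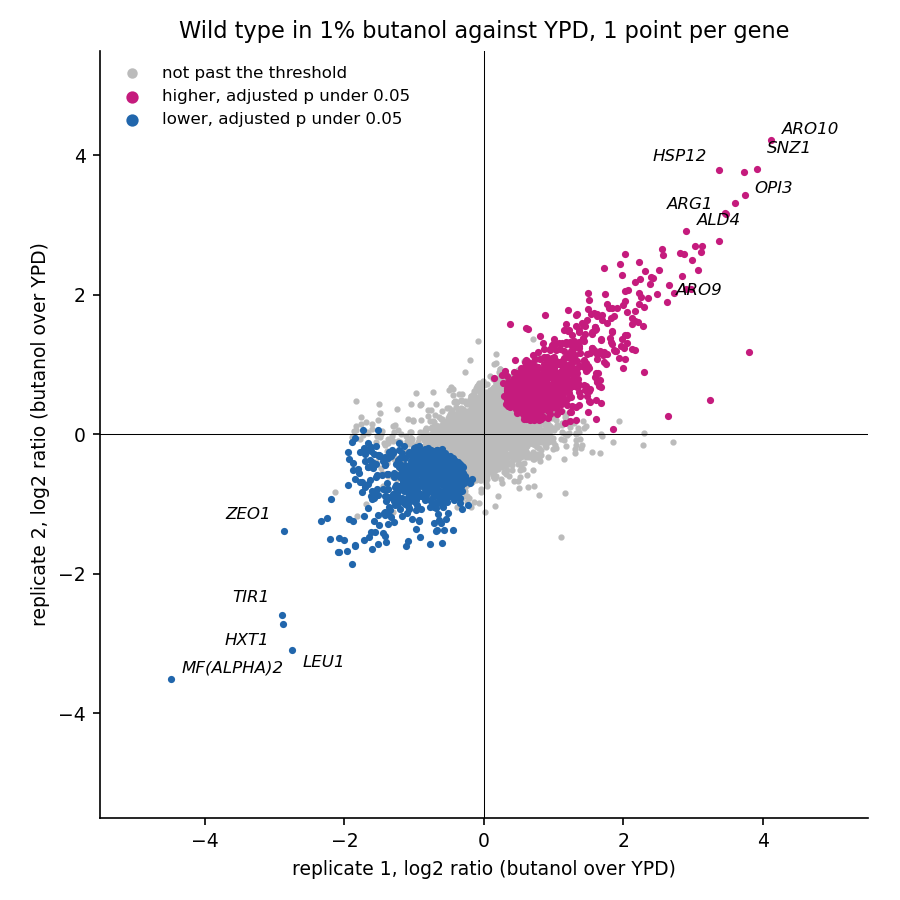
Log2 ratio of butanol over YPD in wild type on the array of replicate 1 (x axis) and replicate 2 (y axis), 1 point per gene, with the 778 genes that passed the test as higher and the 649 that passed as lower in colour. The correlation across genes was 0.750, and ARO10 lay at 4.12 and 4.22.

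The alcohol and aldehyde list of 30 genes had 12 members that rose and 3 that fell, the same counts as when adjusted over the list alone. Its largest increases after ARO10 were those of the aldehyde dehydrogenase gene ALD4 (2.91 ± 0.14), the alcohol dehydrogenase gene ADH5 (2.72 ± 0.20) and the aromatic aminotransferase gene ARO9 (2.43 ± 0.14). Of 44 genes of the Gcn4 amino acid synthesis list, 25 rose and 3 fell (29 and 4 adjusted over the list alone), with ARG3 at 2.86 ± 0.21. Of 40 general stress genes under Msn2 and Msn4, 27 rose and 1 fell (30 and 2 adjusted over the list alone), among them the hexokinase gene HXK1 at 2.56, YGP1 at 2.34 and the polyubiquitin gene UBI4 at 2.15. Of 30 chaperone genes under Hsf1, 14 rose and 1 fell (17 and 1 adjusted over the list alone): SSA1 was at 1.38, HSP26 at 1.34 and HSP82 at 1.24, and the 1 that fell was HSP30 at -1.79. Glucose-repressed genes rose in 12 of 24 cases (13 adjusted over the list alone), with ADH2 at 2.13. Phospholipid genes rose in 7 of 19 cases by either count, with CHO1 at 1.39, ITR1 at 1.32 and CHO2 at 1.20. In the drug resistance list 6 of 17 rose by either count, and the weak-acid transporter gene PDR12 had the largest value, 2.24 ± 0.21.

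Ribosomal protein genes fell in 90 of 138 cases and none rose (120 adjusted over the list alone); their median was -0.82 (-1.53 with median centring), with RPS22B and RPL9A each at -1.56. Ribosome biogenesis genes fell in 45 of 77 cases and none rose (57 adjusted over the list alone), among them DBP2 at -1.55, ENP2 at -1.27 and RRP5 at -1.25. Of 22 pheromone response genes, 11 fell and 1 rose (13 and 1 adjusted over the list alone). FAR1, which arrests the cell cycle during mating, was at -1.48, SST2 at -1.31 and FUS1 at -1.27. PRM10 was not well above background in butanol and was at least 3.30-fold lower there (adjusted p = 0.0046). All 4 alpha-specific genes, MF(ALPHA)2, MF(ALPHA)1 (-1.15), STE3 (-1.28) and SAG1 (-1.02), fell; with fewer than 5 genes that list was not tested as a set. The filamentous growth list had 2 of 29 members that rose, among them DIA3 at 0.99, and 2 that fell, MGA1 at -1.03 and STE12 at -0.99, and its set test gave an adjusted p of 0.953. None of the 5 flocculin genes passed the test, and FLO11 was at -0.14 ± 0.14.

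**Figure D3:**
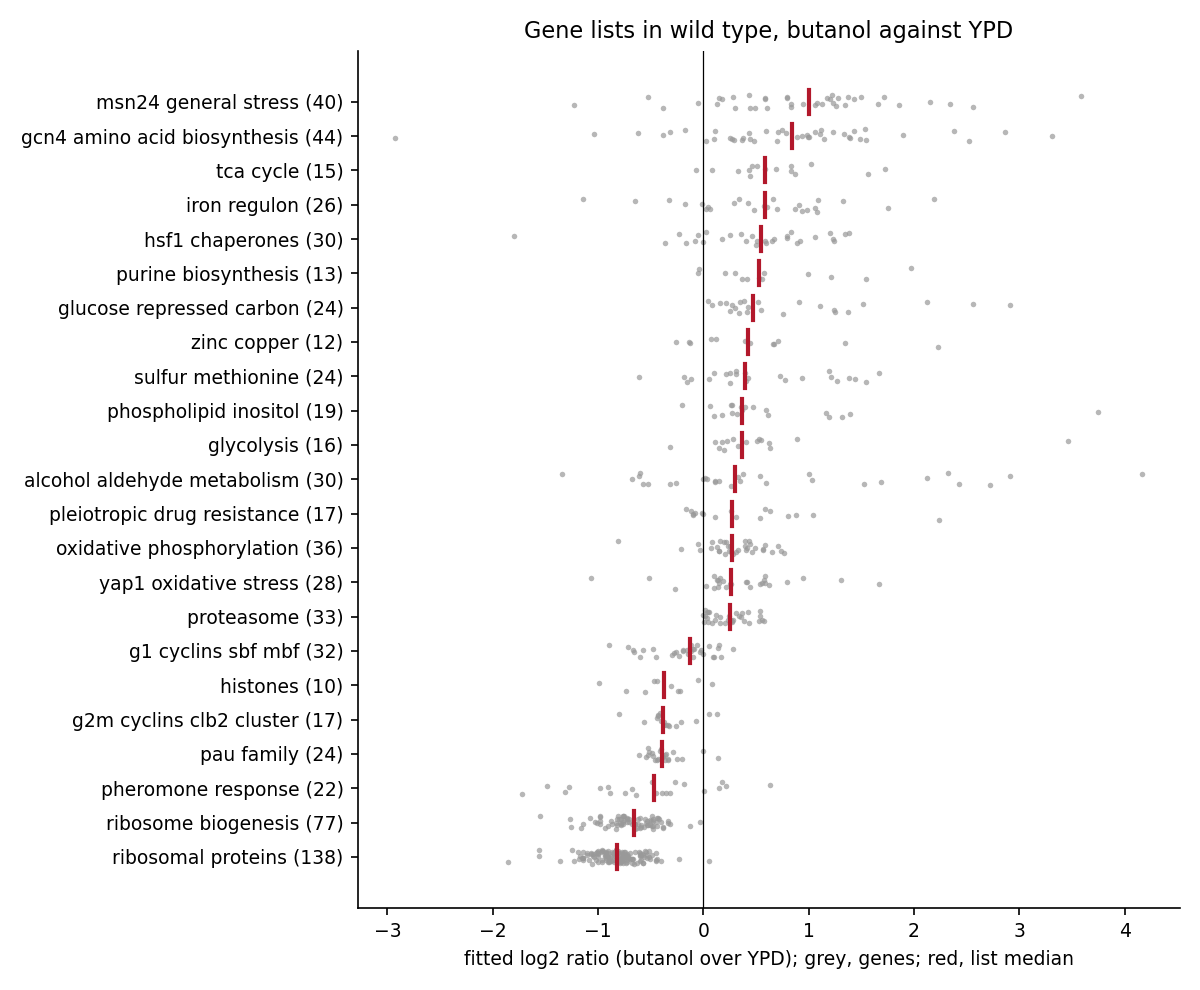
Fitted log2 ratio of butanol over YPD (x axis) for the members of the 23 gene lists that passed the camera set test (y axis, number of tested genes in brackets); grey points are genes and red bars are list medians. The medians ran from -0.82 for ribosomal proteins to 1.00 for Msn2 and Msn4 genes, and glycolysis and the proteasome were the lists whose direction turned with median centring.

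With camera's preset inter-gene correlation, 23 of 37 lists passed in the butanol comparison, 16 up and 7 down. None passed with an estimated correlation: the adjusted p was then 0.301 for ribosomal proteins, ribosome biogenesis and the Gcn4 list, 0.237 for the Msn2 and Msn4 list and for the alcohol list, 0.159 for the Hsf1 and pheromone lists, and 0.175 for the glucose-repressed and phospholipid lists. For drug resistance the adjusted p was 0.301 with an estimated correlation. The 2 arrays had a correlation of 0.750 across genes, which are not independent replicates. The size of the response differed between the arrays for ribosomal proteins, with medians of -1.39 and -0.26. The count of changed genes depended on replicate 1: without it 241 genes passed, of which 235 were among the 1427. With scan as a block 826 genes passed, with slide as a block 1010, and within slide 1 793; within scan 1 and scan 2, each holding 1 array of this comparison, 853 and 68 passed. The fits within a slide or scan also had no dye term. Of the called genes 54.5% were higher, against 79.5% of 366 in the authors' processed values. With the intensity trend removed from those values, 60.8% of 533 were higher. The authors' column for replicate 1 matched neither butanol array by duplicate spots. It had a rank correlation of 0.75 with the array of replicate 2 across spots, which are not independent replicates.

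On the arrays labelled phd1Δ in butanol, PHD1 was the only gene that passed, with a fitted log2 ratio of -3.76 (limma adjusted p = 0.0059). It was not well above background in the Cy5 channel of replicate 2, so only replicate 1, at -4.65, measured it in the deletion library, and the fitted value, a mean with the dim replicate 2 (-2.86), does not give the size of the loss. Among genes of filamentous growth the next largest value was that of the aquaporin gene AQY2, -0.57 and -0.57 on the 2 arrays (adjusted p = 0.998), and FLO11, the flocculin of filamentous growth, was at -0.17 ± 0.14. The neighbours of PHD1 on its chromosome, MMO1, PRI2, SPC42 and VPS24, lay between -0.18 and 0.33, and none passed. Hsf1 chaperone genes had the clearest shift of any list, a median of 0.22 (0.28 and 0.13 on the 2 arrays), with SSA4 at 0.77 ± 0.20, HSP42 at 0.42 and HSP104 at 0.38. The list passed camera with an adjusted p of 7.5e-08, had an adjusted p of 0.0896 with an estimated correlation, and passed fry at 0.0232; none of its 30 genes passed alone, over all genes or adjusted over the list alone.

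In all, 0 genes were higher and 1 lower in limma among 6246, and 75 had an unadjusted p under 0.05. Camera passed 11 lists, 0 with an estimated correlation, and fry passed 1. The call of PHD1 was lost in fits within slide 1 (-3.76, adjusted p = 0.126) and within scan 2 (-2.86, adjusted p = 0.30), which had both fewer arrays and no dye term; the cause was not tested. Log2 ratios of the 2 arrays had a correlation of 0.182 across genes. The genes called here and those called for butanol shared 0 members, which says nothing of a shared response, since the only gene called here was the deleted gene itself. Both comparisons held wild type in butanol, and part of any overlap may come from shared RNA.

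On the arrays labelled xbp1Δ after low peroxide, 1 gene passed, and it was MKT1, which encodes a regulator of translation on the polysome, and not XBP1. MKT1 was at -4.55 and -5.32 on the 2 arrays (-4.94 ± 0.17, 30.6-fold lower, limma adjusted p = 6.3e-06), and between -0.39 and 0.70 on the other 8 arrays. XBP1 was at -0.22 ± 0.20. Hexose transporter genes had lower values on both arrays without passing over all genes: HXT2 at -1.15 and -0.85 on the 2 arrays, HXT7 at -0.97 ± 0.15 and HXT6 at -0.86 ± 0.14 (adjusted p = 0.266 each), and HXT4 at -0.85 ± 0.15 (adjusted p = 0.340). These 4 of 19 genes fell when adjusted over the list alone. HXT6 and HXT7 are near-identical copies that can share signal. G1 cyclin and SBF or MBF target genes, a class to which known Xbp1 targets belong, had a median of 0.03, with CLN1 at -0.31 ± 0.16, and none of 32 passed by either count. The Msn2 and Msn4 list had a median of -0.06, and none of 40 passed by either count, with CTT1 at -0.61 and HSP26 at -0.57.

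Limma called 0 genes as higher and 1 as lower, and 107 genes had an unadjusted p under 0.05, 24 higher and 83 lower. This share too was below 0.05, so the test was conservative and the lack of further calls does not show a lack of effects. Camera passed 15 lists, 3 up and 12 down, 0 with an estimated correlation, and fry passed 1, the Hsf1 chaperones (median -0.15, fry adjusted p = 0.0284; camera adjusted p = 0.128 with an estimated correlation). For hexose transporters the camera adjusted p was 2.4e-05, and 0.479 with an estimated correlation. The correlation of the 2 arrays across genes was -0.196.

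The 2 arrays labelled rox1Δ after high peroxide differed in which gene was missing. On replicate 1, where ROX1 was low, low-oxygen genes that Rox1 represses were higher: ANB1, a translation factor gene of low-oxygen growth, was at 3.42 ± 0.19 (10.7-fold, adjusted p = 3.7e-04) in the fit without replicate 2, HEM13 of haem synthesis at 2.45 ± 0.22 (5.46-fold), TIR1 at 2.25 ± 0.20 and the mannoprotein gene DAN1 at 2.57 ± 0.24. ROX1 itself was lower (adjusted p = 0.0026) and was not well above background in Cy3, so the ratios printed for it are against the floor and do not give the size of its loss. In that fit 6 of the 12 Rox1 targets were higher and 1, HMG2, was 2.31-fold lower; CYC7 and COX5B, at -0.11 and -0.10, did not pass. Also in that fit, which rests on a lone array, the 77 ribosome biogenesis genes had a median of 0.72. Medians were -0.98 for 16 phosphate regulon genes, -0.74 for 15 of the citric acid cycle and -0.22 for 40 under Msn2 and Msn4. They were -0.36 for 27 of cell wall integrity and -0.53 for 26 of the iron regulon, with the iron oxidase gene FET3 at -1.78 ± 0.17. This array had a correlation of 0.50 across genes with replicate 1 of the self comparison, as Cy5 over Cy3. Whether that shared structure explains these medians was examined for ribosome biogenesis alone. Chosen after values were seen, the chaperone-linked gene BTN2 was at 2.19 and the glucokinase gene GLK1 at -2.64.

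On replicate 2, ROX1 was at 0.09 with 16.3 times the local background in its dimmer channel, and GZF3, a GATA repressor of nitrogen catabolite genes, was 23.3-fold brighter in Cy5 (4.55 ± 0.18 in the fit without replicate 1, adjusted p = 2.3e-05). In Cy3, 1 of the 2 GZF3 spots was well above background, and their signal averaged 2.47 times the local background. The ratio therefore lies near the floor and does not give the size of a loss. The Cy3 channel holds the wild type in the printed direction, and the library labelled rox1Δ with the dyes as labelled. Besides GZF3, URA1 was brighter in Cy5. FUI1, DAL4, DAL5 and UGA4 were brighter in Cy3, at -1.38 to -2.51 as Cy5 over Cy3. DAL80 was brighter in Cy3 too, but was well above background on only 1 of the 2 arrays, and no size is given. These 6 genes were chosen after their values were seen. Rox1 targets had a median of 0.02 on this array, against 1.05 on replicate 1. The authors' processed values for replicate 2 differed from this array: in their column ROX1 was at -6.15, ANB1 at 5.28, HEM13 at 3.96, DAN1 at 3.49 and TIR1 at 4.26.

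**Figure D4:**
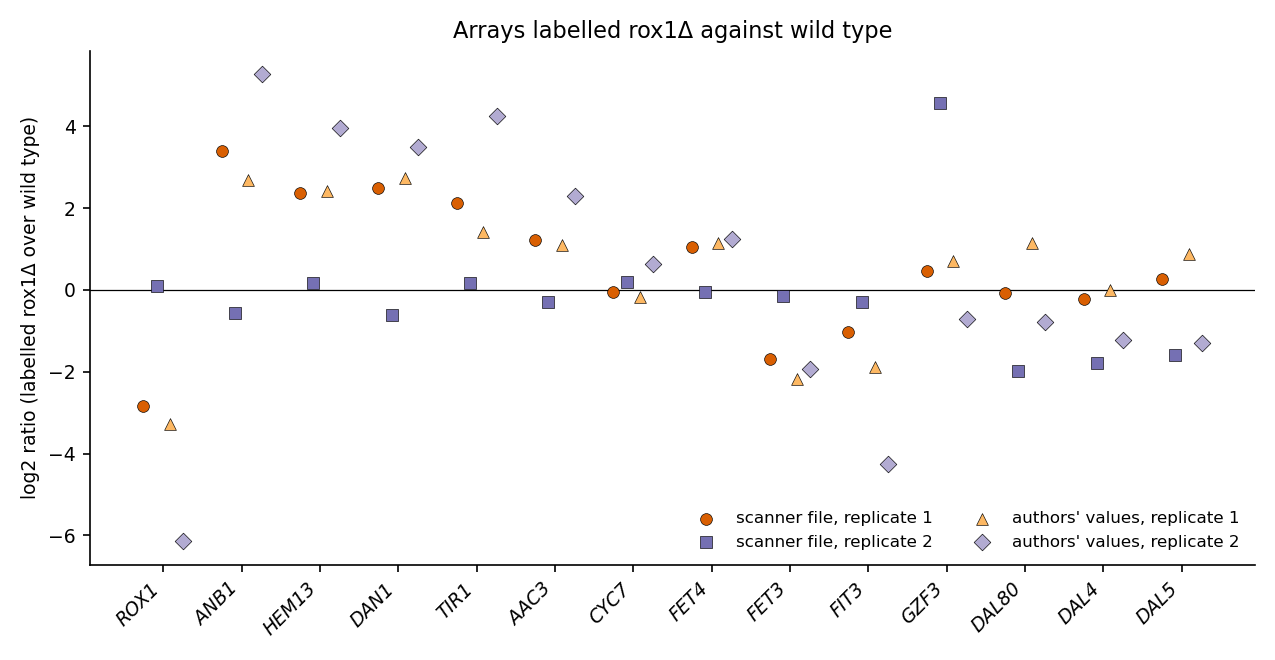
Log2 ratio (y axis) of 14 genes (x axis) on the arrays labelled rox1Δ, from the scanner files and from the authors' processed values, 1 point per replicate and source. ROX1 was at -2.84 and 0.09 in the scanner files and at -3.27 and -6.15 in the authors' values, and ANB1 at 3.40 and -0.57 against 2.69 and 5.28.

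With both arrays together 0 genes passed in limma; 1179 had an unadjusted p under 0.05, 611 higher and 568 lower, and the smallest adjusted p was 0.0588, for ARO10 (1.11 and 1.14 on the 2 arrays, chosen after its values were seen). ROX1 was then at -1.38 ± 0.49 (adjusted p = 0.226), with replicate 1 against the floor, ANB1 at 1.42 ± 0.63 and HEM13 at 1.26 ± 0.39, and the correlation of the arrays across genes was 0.135. Without replicate 2, 953 genes passed (525 higher, 428 lower), and without replicate 1, 7 passed (2 higher, 5 lower), with the lone array assumed to vary like the other comparisons. In the authors' values DAN1 alone passed (3.12 ± 0.24, adjusted p = 0.0270), with ANB1 at 3.98 and HEM13 at 3.19 (adjusted p = 0.0651 each). The authors' 2 columns nevertheless ran opposite across genes, with a correlation of -0.682. In them GLK1 was at -3.11 and 2.48, and BTN2 at 2.15 and -0.88. Their rank correlations with mean signal were -0.35 and 0.45, so these columns do not act as replicates beyond such targets. Camera passed 10 lists for the 2 arrays together, 3 up and 7 down. These list results rest on the direction of replicate 2, which was carried over from replicate 1. Rox1 targets had a median of 0.48 (adjusted p = 0.0387, and 0.781 with an estimated correlation), with 1 of 12 higher adjusted over the list alone. The nitrogen catabolite list, at a median of -0.44 (-0.22 and -0.57 on the 2 arrays, -0.27 in the fit without replicate 2, and 12 of 28 lower and 1 higher adjusted over the list alone), had an adjusted p of 1.2e-07, of 0.141 with an estimated correlation and of 0.0152 in fry, the only list that fry passed. The 11 genes of the anaerobic cell wall and sterol uptake list had a median of -0.02 and a mean of 0.18 (adjusted p = 0.645). The source name of the wild type in this comparison mentions no peroxide, whereas the titles and the growth protocol do; the Msn2 and Msn4 list had medians of -0.18 and -0.04, and the Yap1 list 0.10 and -0.05.

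In the self comparison, wild type in YPD against itself, limma called 0 genes, and 32 had an unadjusted p under 0.05. As a share of all genes tested that is below 0.05, so the gene test was conservative for this comparison. Camera passed 4 lists there with its preset correlation, the Msn2 and Msn4 list up (median 0.20, adjusted p = 1.1e-11), cell wall integrity up (0.11), ribosome biogenesis down (-0.10) and zinc and copper down (-0.04). None of the 4 passed with an estimated correlation (adjusted p = 0.774 for the Msn2 and Msn4 and cell wall lists and 0.927 for the others) or in fry. Medians of this size and a few camera calls were therefore the background of the set tests. The correlation of its 2 arrays across genes was -0.210.

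No gene was called in more than 1 of the 3 deletion comparisons, which with 1, 1 and 0 calls was nearly fixed. At an unadjusted p under 0.01, the comparisons labelled xbp1Δ and rox1Δ shared 4 genes that were lower in both, against 0.566 for independent lists (two-sided Fisher's exact test, p = 0.0023). Those labelled xbp1Δ and phd1Δ shared 1 gene higher in both (Fisher's exact test, p = 0.0077) and 1 higher in the former and lower in the latter (p = 0.0089), so single genes reached such values in either direction. These p values were not adjusted over the pairs of comparisons and directions, and genes are not independent replicates. Whole-chromosome shifts, which would follow the gain or loss of a chromosome, stayed small: 1 of 16 chromosomes in 1 of 5 comparisons passed the permutation test, chromosome 8 for the arrays labelled rox1Δ with a shift of -0.0678 (adjusted p = 0.0288), and it did not pass with median centring (-0.0546), without replicate 1 (-0.0073) or without replicate 2 (-0.0901, adjusted p = 0.132). Without replicate 2, chromosome 4 passed instead, with a shift of 0.0696 (adjusted p = 0.0088).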

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

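All tests in this part were chosen after the results were seen, except the test of a structure shared with the self comparison, whose bound was written before its value and whose interval was added after. 2 results came from data that the comparisons did not use, the authors' processed column labelled rox1Δ replicate 2. ROX1 was at -6.15 in it, where the self comparison columns reached 0.18 in size. The iron regulon had a median of -1.84 in it, against 0.06 in the self comparison columns.

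On both arrays labelled xbp1Δ, MKT1 signal was lost in 1 of the 2 libraries, that labelled xbp1Δ in the printed direction and the wild type with the dyes as labelled (4.94), and XBP1 signal was lost in neither. A defective spot is argued against by the 4 MKT1 spots of the 2 arrays, all 4 of which lay below -4 on the log2 scale. A dead XBP1 probe is argued against by its signal, at least 31.2 times the local background in each channel. An XBP1 log2 ratio of -0.22 beside an MKT1 ratio of -4.94 is what a strain lacking MKT1 and keeping XBP1 would give, so a candidate explanation is that such a strain was hybridised, as the deletion library if the printed direction holds. No biological explanation was tested, and a probe outside the deleted part of XBP1 stays open.

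ROX1 was present in both channels of the array labelled rox1Δ replicate 2. Dim signal is argued against by a ROX1 signal of at least 16.3 times the local background, and a swap within the series by the other 8 arrays outside this comparison, where ROX1 never exceeded 0.26 in size. On this array the 27 nitrogen catabolite genes other than GZF3 had a median Cy5 over Cy3 ratio of -0.57, below the lowest median of 10000 random lists (-0.19). Of the 27, 23 were brighter in the Cy3 channel that lacked GZF3. The random lists held genes drawn singly at like signal, whereas genes under shared control can move together on a lone array. The test therefore cannot tell a loss of GZF3 from another cause of a shift in these genes. A candidate explanation is an array of a strain lacking GZF3, filed under another label. The Cy3 channel holds the wild type in the printed direction, so under this candidate the signs printed for this array would turn. The authors' own column for this sample, with ROX1 at -6.15, points to another array as its origin, and no biological explanation was tested.

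Ribosome biogenesis genes were higher on the array labelled rox1Δ replicate 1, with a median of 0.79. That array and replicate 1 of the self comparison had a correlation of 0.50 across genes as Cy5 over Cy3, and with the self profile regressed out the median was 0.58, a share of 0.74 (bootstrap interval over genes 0.57 to 0.93), while the median of the Rox1 targets, 1.05 before, did not fall. The share itself lay above the bound written beforehand for excluding this structure, so that rule alone would have excluded it. The interval added afterwards held the bound. It resamples genes of a lone array, which are not independent replicates, and does not measure the spread between arrays. A shared array structure and an effect of ROX1 therefore cannot be told apart for these genes. Whether the wild type lacked peroxide cannot be told either: the median of 0.79 is the pattern itself, the Msn2 and Msn4 list had a median of -0.18 here and of 0.02 and 0.36 on the 2 self comparison arrays, and with the dyes as labelled both signs would turn. In the fit without replicate 2, 11 of 40 genes of that list were lower and 1 higher, against 0 called in the self comparison, but the direction stays unsettled, and a biological effect of the missing repressor stays open and untested.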

How the results depend on the processing

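The fits within slides or scans, the fit without the doubted array, the authors' values with their intensity trend removed and the dyes as labelled were chosen after the results were seen. For changed genes, the threshold on |t| set by the self comparison gave 51, 18 and 389 for the arrays labelled xbp1Δ, phd1Δ and rox1Δ, names used here as labels and not as shown genotypes. With probes well above background on all arrays, phd1Δ had 0, since the PHD1 probe was not kept, and rox1Δ 1. Within slide 1 and within scan 2 phd1Δ had 0. For rox1Δ an intensity trend in the variance prior gave 1, the authors' values 1, those with the trend removed 7, and leaving out a replicate 7 to 953. For butanol, against 1427, the values were 826 with scan as a block, 742 with only its 2 arrays, 366 and 533 with the authors' values without and with trend removal, 793 within slide 1, 853 within scan 1, 68 within scan 2, 373 at 2-fold or more, and 241 to 1205 without a replicate; no shared call changed sign. Without the doubted array it had 1916, which kept all 1427. ROX1 ranged from 0.13 without replicate 1 to -2.89 without replicate 2, the latter against a channel not well above background and so not the size of a loss. The fits within a slide or scan had fewer arrays and also no dye term, and the cause of these moves was not tested.

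Lists passed by camera, 15, 11, 10, 23 and 4 for xbp1Δ, phd1Δ, rox1Δ, butanol and the self comparison, were 0 in each with an estimated correlation; fry gave 1, 1, 1, 24 and 0 in one direction and 1, 1, 4, 35 and 0 in either. Median centring gave 18 for phd1Δ and 18 for rox1Δ, trend removal 16 for rox1Δ and 8 for the self comparison, the authors' values 11 for the self comparison, within scan 1 7 for phd1Δ and within slide 1 1 for the self comparison. Leaving out a replicate gave 8 to 11, 5 to 10, 6 to 12, 20 to 22 and 0 to 6. The median turned in some setting in 6 of 15, 5 of 11, 3 of 10 and 1 of 4 lists for xbp1Δ, phd1Δ, rox1Δ and the self comparison. For butanol it turned in 2 of the 23 lists, glycolysis (0.37 to -0.65) and the proteasome (0.25 to -0.10), both with median centring.

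At an unadjusted p under 0.01, phd1Δ and butanol shared 5 genes, 1 of them higher in both and 4 in opposite directions, against 0.721, 0.594, 0.842 and 0.693 for independent lists over the 4 pairs of directions (shared 1, 2, 2 and 0). Chromosomes past the threshold were 0 with median centring and 0 to 1 without a replicate. Reversed values were ENO1 (-0.30), CUP1-2 (-0.03) and CUP1-1 (-0.06) in butanol with median centring, and MKT1 (4.94) and PHD1 (3.76) with the dyes as labelled. Of 96 called named genes, 51 kept their call in the authors' values, 51 without replicate 1, 81 without replicate 2 and 26 of 95 within scan 2.

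Same-numbered deviations had correlations of -0.41 to 0.29 over 10 pairs of comparisons, 2 of them over 0.1. These values do not show a pairing of samples by replicate number. They cannot exclude it, since replicate number went with dye orientation in all comparisons but butanol. With a replicate block in place of the dye term 1549 genes passed in butanol, 1 in xbp1Δ, 1 in phd1Δ, 0 in rox1Δ and 0 in the self comparison. Signal over background limits the dim channels, where PHD1, ROX1 and GZF3 losses lie near the floor.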

Other observations

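Other gene groups moved in wild type given butanol, by lists and tests set before the data were examined. Genes of iron uptake rose in 13 of 26 cases and fell in 2 (16 and 2 adjusted over the list alone), led by the cell wall mannoprotein genes FIT2 (2.19 ± 0.19, 4.56-fold, n = 2 arrays) and FIT3 (1.75 ± 0.18). Copper and zinc genes rose in 6 of 12 cases (7 adjusted over the list alone), with the reductase gene FRE7 at 2.23 ± 0.16 and the copper transporter gene CTR1 at 1.34 ± 0.13. Methionine and sulfur genes rose in 10 of 24 cases (11 adjusted over the list alone), among them MET6 at 1.67 ± 0.27 and MET17 at 1.55 ± 0.22. Purine and one-carbon genes rose in 6 of 13 cases (7 adjusted over the list alone), with SHM2 at 1.97 ± 0.14, and genes of the citric acid cycle in 7 of 15 (8 adjusted over the list alone), with CIT1 at 1.72 ± 0.22 and LSC2 at 1.56 ± 0.13. Each list passed camera but not with an estimated correlation (adjusted p = 0.316 for iron, 0.237 for purines and 0.301 for the other 3).

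Smaller shifts were seen in further lists of that comparison. Over all 6246 genes tested 778 rose and 649 fell. Counts of 5 of 36 that rose, and of 2 of 17 and 1 of 10 that fell, lay near the share over all genes. Yap1 oxidative stress genes rose in 8 of 28 cases and fell in 1 (12 and 1 adjusted over the list alone; adjusted p = 0.175 with an estimated correlation), with the transporter gene ATR1 at 1.67 and GTT2 at 1.31. Oxidative phosphorylation genes rose in 5 of 36 cases and proteasome genes in 6 of 33 (5 and 4 adjusted over the list alone; adjusted p = 0.237 and 0.301 with an estimated correlation), and the direction of the proteasome list turned with median centring. A few cell cycle genes fell, 6 of 32 G1 genes, with the cyclin gene CLB6 at -0.89, 2 of 17 of the CLB2 cluster, with HOF1 at -0.80, and 1 of 10 histone genes, HTA2 at -0.73 (6, 1 and 1 adjusted over the list alone; adjusted p = 0.237, 0.301 and 0.301 with an estimated correlation). In the seripauperin family 5 of 24 fell (9 adjusted over the list alone; adjusted p = 0.435 with an estimated correlation), though these near-identical genes can share signal. TDH1 was the member of glycolysis with the largest increase, and 3 of 16 rose by either count (adjusted p = 0.434 with an estimated correlation); the list's direction turned with median centring.

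In butanol LEU1 of leucine synthesis fell by 2.92 while LEU4, chosen after its value was seen, was at 0.99 ± 0.24. The branched-chain aminotransferase genes also parted, with the mitochondrial BAT1 at -1.03 ± 0.26 and the cytosolic BAT2 at 2.32 ± 0.23, likewise chosen after their values were seen. Each of these 4 genes passed the test over all genes and had the same sign on both arrays. No explanation was tested.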
